A study of Mus musculus with 18 samples.

How the data were processed

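Liver RNA from 18 samples in 6 groups of 3 biological replicates was sequenced. Per the labels' protocols, the mice received tamoxifen at 10 mg/mL on 5 days at an age of 8 weeks, livers were taken at ZT8 (8 hours after lights on), and total RNA was extracted with Trizol and made into Illumina libraries. The authors deposited 1 table of raw read counts per gene, with whole numbers, no normalization and 1 column per library. Per the submitters' processing notes, reads were aligned with STAR 2.6 to the mouse genome build mm10. The read counter, its annotation, its treatment of strand and of reads that match several places, the library kit and the read length are not given in the sources used here. Counts of close paralogs, pseudogenes, overlapping genes and antisense genes are therefore uncertain.

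Each sample was placed in a group by its label alone. The groups are H-WT and H-KO (10 weeks old, a line carrying an Hnf4a allele made for conditional deletion), BH-WT and BH-KO (10 weeks old, a line carrying such alleles of Arntl and Hnf4a), and BH-HF-WT and BH-HF-KO (the latter line at 45 weeks, fed a high-fat diet from 10 weeks of age for 35 weeks). Both lines carry a tamoxifen-activated Cre recombinase at the albumin gene in the strain label. The WT and KO samples of each setting have the same strain label, so what set the WT mice apart is not given in the sources used here. No sample was left out and all 18 columns were used.

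The table held 52636 gene IDs, of which 22756 had no count in any library. Genes were tested after edgeR's filterByExpr by group with a minimum count of 10, which kept 13958 genes and left 38678 untested. Of the IDs, 52403 are in GENCODE M21 (mm10), including 13940 of the tested genes, and coordinates were taken from there, counted from 1. Symbols are those the deposited table pairs with the IDs. Total counts ranged from 6846471 to 9816124 per library. A count of 0 therefore allowed up to 3 counts, or 0.306 to 0.438 CPM (the usual scaled count), relative to the plain total of a library. The CPM values given for genes are relative to the total multiplied by the TMM scaling factor of the library (0.83 to 1.38). On their scale the floor is higher where the factor is under 1 and lower where it is over 1. Such floors cover counting error only. Where all libraries of a group were at 0, the fold was computed against 3 counts over the group's 3 libraries and is given as a lower bound.

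Counts were compared with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM factors, 1 mean per group was fitted to all 18 libraries with 12 residual degrees of freedom, and each contrast was tested with the robust quasi-likelihood F-test, which is two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene passed at an adjusted p under 0.05. Log2 fold changes are given with their standard error (SE), and CPM values as mean ± SD of 3 libraries. There were 8 comparisons, 3 of KO with WT, 2 of the difference between KO effects (interaction contrasts), and 3 between settings.

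A set of 40 gene lists covering liver pathways and marker genes of other cell types was tested with camera in limma 3.58.1 on voom-transformed counts, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Camera asks whether a list's genes moved more than other genes did. It was run again with a correlation estimated from the data, and with fry, which asks whether a list's genes move, on balance, one way. Members of a list were also adjusted over the list alone. The groups, the comparisons, the tests, the lists and the rule for naming genes were chosen before the data were examined. The text names Hnf4a and Arntl, and the 8 (KO against WT) or 6 (other comparisons) largest rises and falls among genes that passed, with at least 5 CPM in 1 group, no overlap between groups (not required for interactions) and a symbol other than a clone name. It further names up to 4 members of each described list (the 2 largest rises and 2 largest falls that passed, or the smallest p) and any core clock gene. Not all genes eligible under the rule are described, and some are not reported here.

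The alternatives were DESeq2 size factors and upper-quartile factors for scaling, no filter and a stricter filter on low counts (1 CPM in 3 libraries), DESeq2 1.42.0 and limma-voom as tests, the fit of the compared groups alone, sex as a covariate, the replicate number as a block, stricter thresholds, and leaving out each library in turn. Leaving out the pair BH-KO replicate 1 and H-WT replicate 3, and the list tests without each library, were added after the data were seen. So were the counting intervals for genes with few counts in a group. The simulation described below was written or revised after the real data had been run once. The same test was applied to other splits of the compared libraries, up to 100 per comparison.

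The tests were also run on simulated counts with known changes, with 13562 genes tested. Far fewer genes were changed than passed in H-KO or BH-KO, so the shares recovered hold for the simulated setting only. For H-KO against H-WT, 41.5% of the genes changed 2-fold and 73.2% of those changed 4-fold were recovered, and 3 of 13366 unchanged genes were called. The shares were 53.0% and 83.3% for BH-HF-KO against BH-HF-WT, 24.6% and 54.9% for the difference between the BH and H effects, and 19.7% and 75% for that between the BH-HF and BH effects. For genes changed 1.5-fold they were 5%, 14.1%, 1.67% and 1.41% in the same order of comparisons, starting with H-KO. Of pairs of libraries within a group, none agreed within sampling noise, with a chi-square per degree of freedom of 8.21 to 128. These values argue against copies of 1 library. That the libraries come from separate mice rests on the labels, and each library was counted as 1 sample.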

Results

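Liver transcriptomes were measured by RNA sequencing in 18 mouse liver samples, 3 biological replicates in each of 6 groups, all taken at ZT8. The H groups came from a line with a conditional allele of Hnf4a, which encodes a nuclear receptor of hepatocytes. The BH groups came from a line with conditional alleles of Hnf4a and of Arntl (Bmal1), which encodes an activator of the circadian clock. H and BH mice were sampled at 10 weeks, 2 weeks after the age of tamoxifen treatment, and the BH-HF groups, of the BH line, at 45 weeks after 35 weeks of high-fat diet. Total counts per library were 7537593 to 8548626 in H-WT, 6860759 to 7587070 in H-KO and 6846471 to 8618642 in BH-WT. They were 7660801 to 8757684 in BH-KO, 8124912 to 9431965 in BH-HF-WT and 7569499 to 9816124 in BH-HF-KO. The first principal component of 13958 genes held 48.3% of the variance and the second 15.1%. Xist, the RNA of the inactive X chromosome, was at 1084 CPM in H-WT replicate 3 and at or below 3.9 CPM in the other 17 libraries. Ddx3y, a gene of the Y chromosome, was at 5.74 CPM in that library and at 115 to 185 CPM in the others, so 1 of the 3 H-WT libraries had the pattern of a female and all H-KO libraries that of males. Throughout, CPM values are means ± SD (n = 3) and log2 fold changes are given ± SE. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They judge a difference against the spread between biological replicates estimated over all 6 groups together, not over the compared groups alone.

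The targeted genes were examined first, over the whole gene. Deletion removes only part of each gene, so gene-level counts check the labels only weakly. Hnf4a (ENSMUSG00000017950, mm10 chromosome 2, 163506808 to 163572910) gave 593 ± 56.3 CPM in H-KO and 757 ± 159 in H-WT (log2 fold change -0.35 ± 0.21, adjusted p = 0.208). It gave 621 ± 213 in BH-KO and 817 ± 63.6 in BH-WT (-0.40 ± 0.21, adjusted p = 0.164), and 881 ± 85.5 in BH-HF-KO and 797 ± 38.1 in BH-HF-WT (0.14 ± 0.21, adjusted p = 1). Single libraries ranged from 581 to 889 in H-WT, 556 to 658 in H-KO, 772 to 890 in BH-WT, 495 to 867 in BH-KO, 768 to 840 in BH-HF-WT and 820 to 978 in BH-HF-KO. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126) rose in BH-KO, to 21.3 ± 3.47 CPM against 0.652 ± 0.203 in BH-WT (log2 fold change 5.00 ± 0.43, adjusted p = 2.13e-06). The 3 BH-KO libraries lay between 17.4 and 24.1 CPM and the other 15 at or below 2.61. In H-KO it gave 2.4 ± 0.301 against 1.61 ± 0.853 CPM (0.57 ± 0.39, adjusted p = 0.284), and in BH-HF-KO 1.59 ± 0.849 against 1.47 ± 0.496 CPM (0.13 ± 0.42, adjusted p = 1). The libraries labelled BH-HF-KO thus lacked the Arntl level of the BH-KO libraries, which goes against their label, and this bears on every direction drawn from them.

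**Figure D1:**
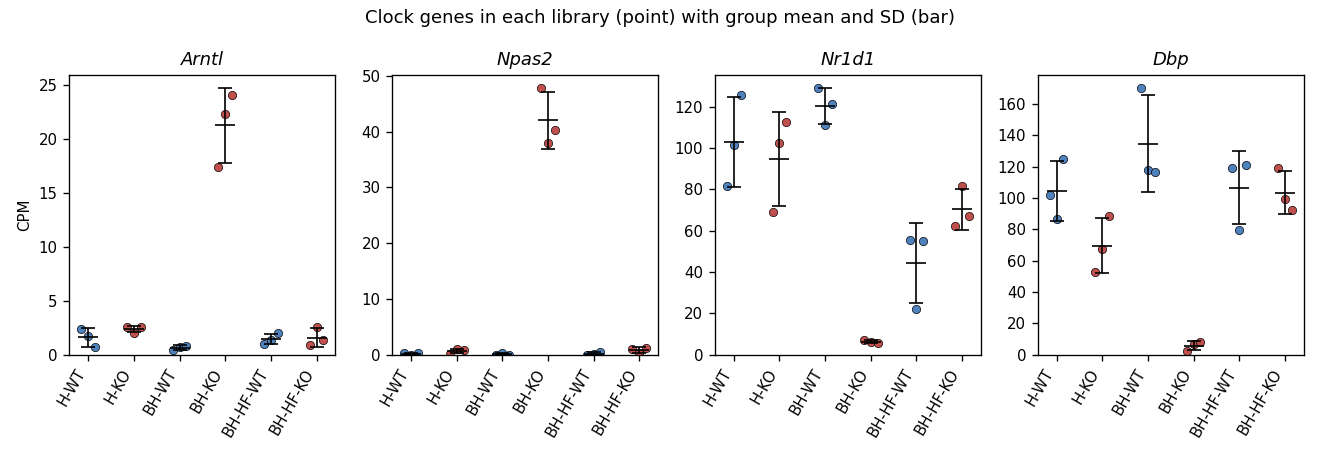
CPM (linear axis) of Arntl, Npas2, Nr1d1 and Dbp in the 18 libraries (points) of the 6 groups, with group mean and SD (bars). The 3 BH-KO libraries stand apart in each panel, with Arntl between 17.4 and 24.1 CPM and Nr1d1 between 5.64 and 6.98 CPM, while the other 15 libraries hold Nr1d1 at 22.1 to 129 CPM.

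The comparison of H-KO with H-WT asks how livers labelled KO in the H line differed from WT at 10 weeks. Genes of several hepatocyte functions fell. Apoa2 (ENSMUSG00000005681, chromosome 1, 171225054 to 171226379), an apolipoprotein of high-density lipoprotein, fell from 5073 ± 966 to 129 ± 16.9 CPM (log2 fold change -5.29 ± 0.97, adjusted p = 0.000917). Otc (ENSMUSG00000031173, chromosome X, 10252305 to 10321024), an enzyme of the urea cycle, fell from 559 ± 164 to 17.4 ± 3.72 CPM (-5.01 ± 0.87, adjusted p = 0.00076). Slc27a5 (ENSMUSG00000030382, chromosome 7, 12988346 to 12998192), which activates bile acids for conjugation, fell from 822 ± 156 to 25.7 ± 4.76 CPM (-5.00 ± 0.82, adjusted p = 0.000509). Hsd3b2 (ENSMUSG00000063730, chromosome 3, 98709255 to 98724543), a steroid dehydrogenase, fell from 65.4 ± 7.8 to 0.3 ± 0.166 CPM (-7.68 ± 1.67, adjusted p = 0.00315). Sfrp4 (ENSMUSG00000021319, chromosome 13, 19623104 to 19632994), a secreted Wnt antagonist with no count in H-WT, was at least 130-fold higher at 17.1 ± 2.28 CPM (adjusted p = 0.000556). Sorcs2, a sorting receptor, rose from 0.176 ± 0.0779 to 59.1 ± 3.63 CPM (8.27 ± 1.24, adjusted p = 0.000277). In total 4871 of 13958 genes passed, with 2209 that rose and 2662 that fell, 978 and 1365 of them at least 2-fold, and 6188 genes had an unadjusted p under 0.05. The groups did not overlap for 51.9% of the tested genes, where chance gives 10%. Upper-quartile scaling moved the median log2 fold change of all genes by 0.15 and gave 3338 rises and 2063 falls. The count was 4015 without H-WT replicate 3, the library with the female pattern, and 3994 with sex as a covariate. The covariate marks that library alone, so here and below it is nearly the same check as leaving the library out. Leaving out any 1 library of the 2 groups gave 3787 to 4284 genes, so these counts do not single out sex. Albumin took 1.54 ± 0.169% of counts in H-KO and 7.33 ± 0.491% in H-WT, mitochondrially encoded genes took 4.46 to 5.18% and 7.42 to 8.54%, and the TMM factors were 1.32 to 1.38 and 0.949 to 0.95.

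**Figure D2:**
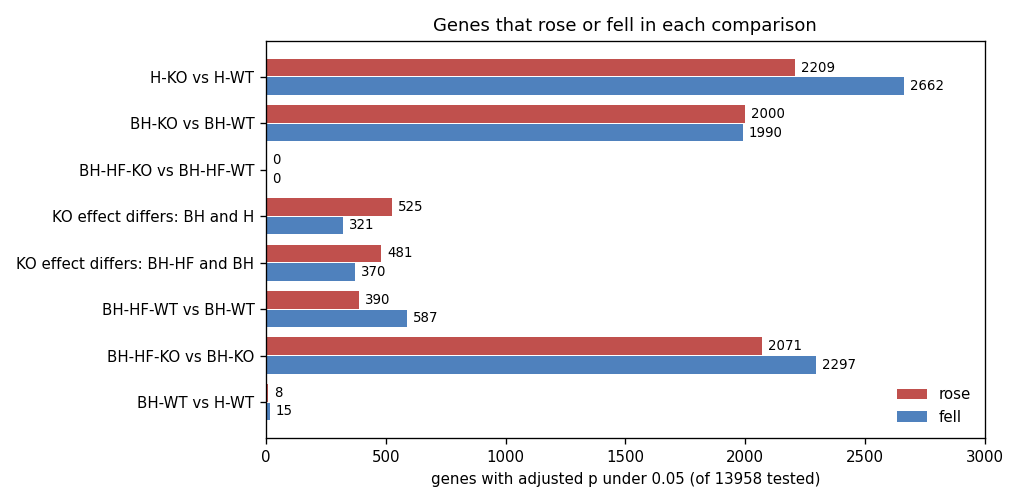
Number of genes (horizontal axis, linear) that rose (red) or fell (blue) at an adjusted p under 0.05 in each of the 8 comparisons, of 13958 tested; for the 2 KO effect comparisons, rose means a higher effect in the first-named setting. The bars reach 2209 and 2662 for H-KO against H-WT, 2000 and 1990 for BH-KO against BH-WT, and 0 and 0 for BH-HF-KO against BH-HF-WT.

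In H-KO camera called 13 lists lower and 2 higher. None of these calls held with an estimated correlation (adjusted p of 0.473 at the lowest, with 0.528 for the HNF4A-dependent, cholesterol and P450 lists, 0.473 for the urea cycle, bile acid and pericentral lists and 0.551 for the gluconeogenesis list). Of 38 genes of the HNF4A-dependent list, 28 fell, 2 rose and 8 did not pass (31 passed adjusted over the list alone, median log2 fold change -2.09, camera adjusted p = 6.23e-09). The near-identical carboxylesterases Ces3b and Ces3a, whose counts are uncertain, fell from 310 ± 175 to 0.638 ± 0.182 and from 1267 ± 354 to 7.16 ± 3.17 CPM. Of 25 cholesterol synthesis genes, 21 fell and 4 did not pass (23 adjusted over the list alone, median -1.73, camera adjusted p = 8.27e-10). They included Stard4, a sterol carrier, with -3.57 ± 0.38 (adjusted p = 1.94e-05). Of 50 cytochrome P450 and drug metabolism genes, 35 fell, 1 rose and 14 did not pass (38 adjusted over the list alone, median -3.47, or -3.16 with genes at 0 in a group set to their bound, camera adjusted p = 2.17e-07). Between 24 and 31 of these genes fell without 1 library, and 26 without H-WT replicate 3. The sulfotransferase Sult2a8 fell from 882 ± 110 to 9.65 ± 5.78 CPM. Of 30 genes of the urea cycle and amino acid breakdown, 21 fell, 1 rose and 8 did not pass (23 adjusted over the list alone, median -0.89, camera adjusted p = 2.17e-07). Haao, of tryptophan breakdown, fell from 332 ± 44.3 to 7.44 ± 2.02 CPM, while Arg1, the last enzyme of the urea cycle, rose from 1241 ± 319 to 2703 ± 182 CPM (1.12 ± 0.25, adjusted p = 0.00253). Bile acid synthesis and conjugation had 10 of 14 genes that fell and 4 that did not pass (10 adjusted over the list alone, median -1.64, camera adjusted p = 4.68e-05). Baat, which joins bile acids to taurine, was at 10.5 ± 0.56 against 294 ± 13.8 CPM. Of 20 pericentral hepatocyte genes, 14 fell, 1 rose and 5 did not pass (16 adjusted over the list alone, median -1.24, camera adjusted p = 1.08e-05). The gluconeogenesis and glycogen list had 9 of 17 genes that fell, 1 that rose and 7 that did not pass (10 adjusted over the list alone, median -0.59, camera adjusted p = 0.0282). This call was lost without H-WT replicate 3 (adjusted p = 0.0672), and 5 genes fell without H-KO replicate 1. Of the 15 lists that camera called here, fry called 13. Lists of fat synthesis (6 of 22 rose, 7 fell), lipid droplets and fatty acid uptake (7 of 25 rose, 8 fell) and fatty acid oxidation (5 of 29 rose, 10 fell) were not called (adjusted p = 0.774, 0.872 and 0.305). Of their members, 15, 18 and 17 passed adjusted over the list alone, and 3 fat synthesis genes rose without H-KO replicate 3 or H-WT replicate 2. The medians were 0.03, 0.18 and -0.22, the mean of the lipid droplet list was -0.07, and camera placed the fat synthesis list lower. Without 1 library, risers numbered 1 in the HNF4A-dependent list (without H-KO replicate 2 or 3 or any H-WT replicate) and 2 in the urea cycle and P450 lists (without H-WT replicate 3).

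Lists of liver-enriched transcription factors and clock genes were also called lower in H-KO. Of 21 liver-enriched transcription factors, 9 fell, 3 rose and 9 did not pass (14 adjusted over the list alone, median -0.64, camera adjusted p = 0.0149, adjusted p = 0.528 with an estimated correlation). The xenobiotic receptor Nr1i3 (CAR) fell from 42.3 ± 9.95 to 1.21 ± 0.41 CPM (-5.10 ± 0.86, adjusted p = 0.000637). Of 24 clock genes, 10 fell, 1 rose and 13 did not pass (13 adjusted over the list alone, median -0.56, camera adjusted p = 0.00146, adjusted p = 0.473 with an estimated correlation). The deubiquitinase Usp2 fell (-2.18 ± 0.29, adjusted p = 9.45e-05). Nr1d1 (-0.12 ± 0.27, adjusted p = 0.775), Dbp (-0.59 ± 0.28, adjusted p = 0.121) and Cry1 (-0.28 ± 0.39, adjusted p = 0.624) did not pass. The cell cycle inhibitor Cdkn1a rose from 1.13 ± 0.259 to 22.2 ± 5.04 CPM (4.26 ± 0.42, adjusted p = 1.15e-05). The glycolytic hexokinase Hk2 rose from 1.68 ± 1.09 to 28.2 ± 7.85 CPM (4.06 ± 0.67, adjusted p = 0.000474). Sox9, a factor of bile duct cells, rose from 3.15 ± 0.82 to 38.2 ± 4.26 CPM (3.60 ± 0.47, adjusted p = 9.21e-05). Lists of macrophage (3 of 28 rose), cholangiocyte (4 of 12 rose, 1 fell), stellate cell and matrix (1 of 32 rose, 3 fell) and endothelial genes (0 of 23 passed) were not called by camera (adjusted p = 0.385, 0.264, 0.774 and 0.204). Of their members, 1, 6, 4 and 0 passed adjusted over the list alone. The medians of the macrophage and stellate lists, -0.05 and -0.01, lay below 0 and their means, 0.25 and 0.05, above it, and both medians were above 0 with upper-quartile scaling. Without 1 library, 1 transcription factor rose (H-KO replicate 2 or 3, H-WT replicate 1 or 2) and no clock gene did (H-WT replicate 1 or 2). Likewise 1 macrophage gene rose (H-KO replicate 1 or H-WT replicate 2), 2 cholangiocyte genes rose (H-KO replicate 1 or 3, H-WT replicate 1 or 2) with none falling (H-KO replicate 1 or 2), and no stellate gene rose (H-KO replicate 3 or H-WT replicate 2). Without H-WT replicate 1, 4 endothelial genes fell.

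The comparison of BH-KO with BH-WT asks how livers labelled KO in the BH line differed from WT at 10 weeks. Arntl rose and Hnf4a did not pass, and other clock genes changed in both directions. Npas2 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236), a paralog of Clock that pairs with BMAL1, rose to 42 ± 5.15 CPM from 0.123 ± 0.212 CPM (adjusted p = 2.06e-06). BH-WT held 3 counts of it in all, which gives a ratio of 296 with a 95% counting interval of 101 to 1438. Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), which encodes the repressor REV-ERB alpha, fell from 120 ± 8.91 to 6.24 ± 0.682 CPM (log2 fold change -4.28 ± 0.32, adjusted p = 9.36e-07). The output regulator Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) fell from 135 ± 30.7 to 5.84 ± 2.83 CPM (-4.48 ± 0.33, adjusted p = 8.98e-07). The repressor Cry1 rose from 11.4 ± 1.52 to 107 ± 21.2 CPM (3.23 ± 0.39, adjusted p = 6.88e-05). Of 24 clock genes, 6 rose, 12 fell and 6 did not pass (20 adjusted over the list alone, median -0.69, camera adjusted p = 0.00515, adjusted p = 0.572 with an estimated correlation). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727) rose from 1.01 ± 0.197 to 126 ± 26.4 CPM (6.93 ± 0.43, adjusted p = 1.74e-07). Slc2a5 (ENSMUSG00000028976, chromosome 4, 150119283 to 150144169), a fructose transporter, fell from 14.3 ± 1.01 to 0.367 ± 0.336 CPM (-5.41 ± 0.36, adjusted p = 1.74e-07). Tox2, a chromatin protein, rose from 0.304 ± 0.267 to 11.6 ± 0.529 CPM (5.12 ± 0.48, adjusted p = 5.05e-06). In total 3990 genes passed, with 2000 that rose and 1990 that fell, 740 and 1053 of them at least 2-fold, and 5747 had an unadjusted p under 0.05. The groups did not overlap for 34.9% of the tested genes, against 10% by chance. Upper-quartile scaling gave 2560 rises and 1720 falls. The count was 2330 without BH-KO replicate 2, 2416 without BH-KO replicate 3, 6198 without BH-KO replicate 1 and H-WT replicate 3, a pair chosen after the data were seen, and 1096 with BH-WT and BH-KO fitted alone.

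Lists of amino acid breakdown, fat synthesis and fatty acid oxidation were called lower in BH-KO by camera, and that of gluconeogenesis was not called. The calls of these 3 lists and of the liver-enriched factors below did not hold with an estimated correlation (adjusted p = 0.572 for each). Of 17 genes of gluconeogenesis and glycogen, 6 fell, 2 rose and 9 did not pass (9 adjusted over the list alone, camera adjusted p = 0.0847). The glucose transporter Slc2a2 fell from 535 ± 45 to 123 ± 14.9 CPM (-2.12 ± 0.19, adjusted p = 4.54e-06) and Gys2, liver glycogen synthase, from 361 ± 59.8 to 37.8 ± 25.8 CPM (-3.26 ± 0.38, adjusted p = 4.48e-05). Of 30 urea cycle and amino acid breakdown genes, 10 fell and 20 did not pass (10 adjusted over the list alone, median -0.68, camera adjusted p = 0.00138). Asl, which makes arginine, was at 193 ± 26.9 against 591 ± 79 CPM (-1.62 ± 0.16, adjusted p = 8.8e-06). Of 22 genes of fat synthesis, 6 fell and 16 did not pass (6 adjusted over the list alone, median -0.27, camera adjusted p = 0.0118). The lipogenic regulator Thrsp was at 53.3 ± 19.6 against 546 ± 128 CPM (-3.36 ± 0.40, adjusted p = 4.05e-05). Of 29 genes of fatty acid oxidation and ketogenesis, 12 fell, 3 rose and 14 did not pass (17 adjusted over the list alone, median -0.53, camera adjusted p = 0.00138). Ppara, the receptor that activates this pathway, fell (-2.14 ± 0.39, adjusted p = 0.00138). Pdk4, a kinase that shuts pyruvate out of the citrate cycle, rose from 2.52 ± 1.22 to 66.1 ± 50.8 CPM (4.69 ± 0.77, adjusted p = 0.000814). Of 21 liver-enriched transcription factors, 9 fell, 2 rose and 10 did not pass (13 adjusted over the list alone, camera adjusted p = 0.0413). Cebpa (ENSMUSG00000034957), a factor of hepatocyte identity, fell from 401 ± 71.7 to 87.1 ± 1.24 CPM (-2.20 ± 0.13, adjusted p = 7.26e-08). The transcription factor call was lost without BH-KO replicate 2 or 3 or BH-WT replicate 1 or 3 (adjusted p between 0.0158 and 0.0676 over the libraries left out). Without BH-KO replicate 2 or 3, 5 factors fell, and 1 rose without BH-WT replicate 2. A single fatty acid oxidation gene rose without BH-KO replicate 2 or 3 or BH-WT replicate 1 or 3, a urea cycle gene rose without BH-KO replicate 1 (1 gene), and a fat synthesis gene without BH-KO replicate 1 or BH-WT replicate 2 (1 gene).

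None of the 22 lists that camera called in BH-KO was called with an estimated correlation (adjusted p = 0.576 for the macrophage list and 0.572 for the HNF4A-dependent, P450, cell cycle and p53 lists). The camera calls of these 5 held without each library, while the number of members that passed moved with single libraries in most of them. Of 38 HNF4A-dependent genes, 8 fell, 1 rose and 29 did not pass (7 adjusted over the list alone, median -0.92, camera adjusted p = 5.74e-05). Of 50 P450 and drug metabolism genes, 13 fell, 1 rose and 36 did not pass (12 adjusted over the list alone, median -0.84, camera adjusted p = 2.13e-05). Without BH-KO replicate 1, 26 and 29 members fell. The falls numbered 3 and 5 without BH-KO replicate 2, 3 and 6 without BH-KO replicate 3, 5 and 7 without BH-WT replicate 2, and 4 and 8 without BH-WT replicate 3, with 5 in the former list without BH-WT replicate 1. No HNF4A-dependent gene rose without BH-KO replicate 2 or BH-WT replicate 2 or 3, and no P450 gene without BH-KO replicate 2 or 3 or BH-WT replicate 1 or 2. Of 38 cell cycle genes, 14 rose, 1 fell and 23 did not pass (16 adjusted over the list alone, median 1.04, camera adjusted p = 6.66e-05, adjusted p = 0.572 with an estimated correlation). E2f8, a repressor of the E2F family, rose (2.52 ± 0.57, adjusted p = 0.00572). The rises numbered 24, 3 and 8 without BH-KO replicates 1, 2 and 3 and 8, 9 and 8 without BH-WT replicates 1, 2 and 3, and no member fell without BH-KO replicate 3 or BH-WT replicate 1. Of 21 p53 target genes, 12 rose, 2 fell and 7 did not pass (15 adjusted over the list alone, median 0.75, camera adjusted p = 0.00498), and 1 fell without BH-KO replicate 3. Of 28 macrophage and Kupffer cell markers, 11 fell, 2 rose and 15 did not pass (14 adjusted over the list alone, median -1.44, camera adjusted p = 0.00138). The falls numbered 18 without BH-KO replicate 1, 2 without replicate 2, 4 without replicate 3 and 3 without BH-WT replicate 2. The same list was called higher in BH-WT than in H-WT (median 1.52, camera adjusted p = 3.66e-11, adjusted p = 0.882 with an estimated correlation). Spp1, a secreted matrix protein also made by bile duct cells, rose (2.39 ± 0.48, adjusted p = 0.00289). Camera also called lower the endothelial list (6 of 23 fell, 17 did not pass, 6 adjusted over the list alone, median -0.60, adjusted p = 0.018). The stellate list (4 of 32 fell, 28 did not pass, 0 over the list alone, median -0.31) and the neutrophil list (1 of 8 fell, 7 did not pass, 0 over the list alone, median -1.88) were called lower too (adjusted p = 0.0152 for both). The adjusted p with an estimated correlation was 0.645, 0.652 and 0.572 for these 3. The endothelial call was lost without BH-WT replicate 2 (adjusted p = 0.211), the stellate call without BH-KO replicate 2 or 3 or BH-WT replicate 2 (up to 0.268), and the neutrophil call without BH-KO replicate 3 (0.0634). Endothelial falls numbered 1, 2 and 0 without BH-KO replicate 2, BH-KO replicate 3 and BH-WT replicate 2. Without BH-KO replicates 1, 2 and 3, stellate falls numbered 12, 1 and 0 and neutrophil falls 5, 0 and 0, with 0 of both without BH-WT replicate 2 and 0 neutrophil falls without BH-WT replicate 3. Of the 22 lists, fry called 15. Albumin took 3.71, 2.36 and 1.79% of counts in BH-KO replicates 1, 2 and 3 and 7.73 ± 0.932% in BH-WT, and mitochondrially encoded genes took 9.45, 3.7 and 4.17% in those replicates and 7.2 to 7.66% in BH-WT.

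**Figure D3:**
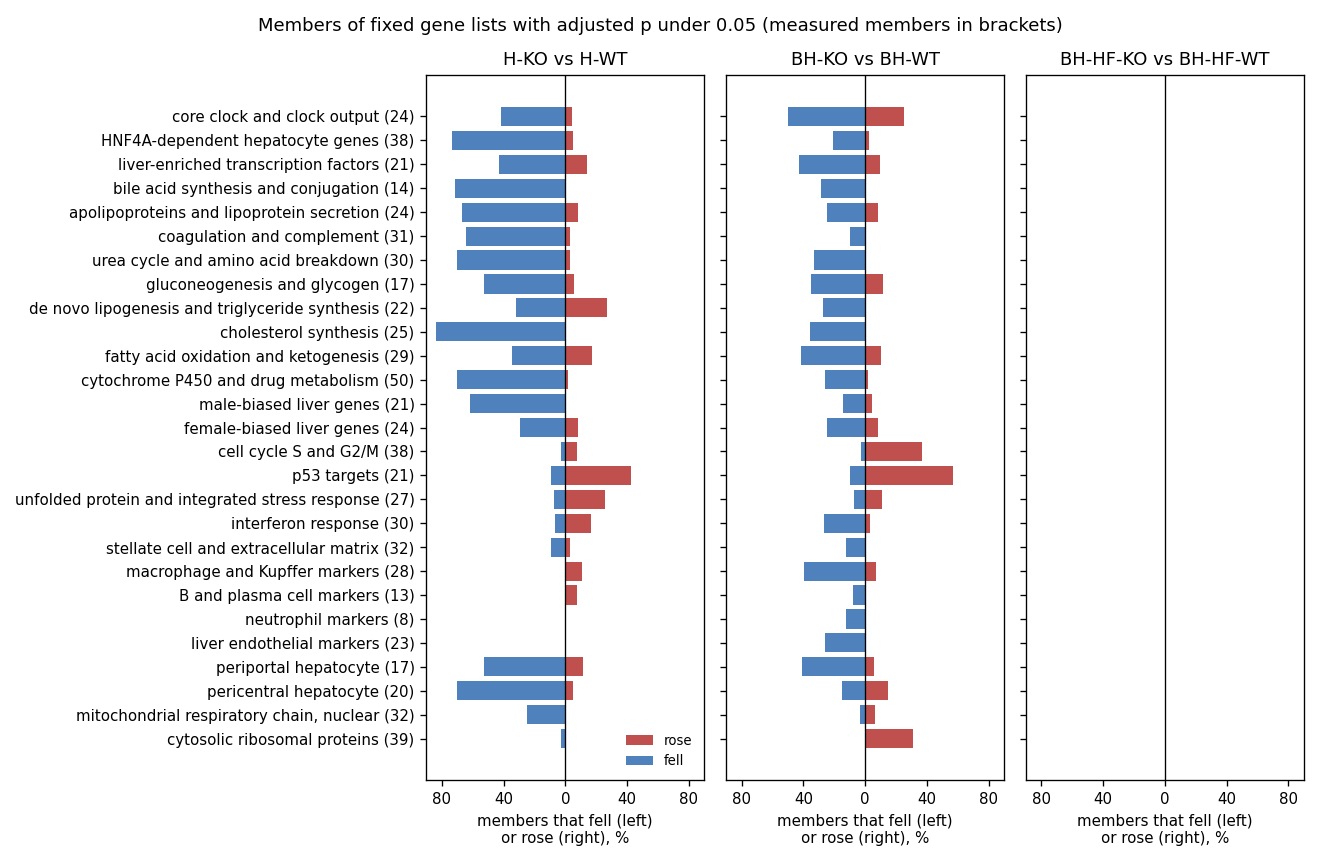
Percent of measured members (horizontal axis, linear) of fixed gene lists (vertical axis, members in brackets) that fell (blue, left) or rose (red, right) at an adjusted p under 0.05 in the 3 comparisons of KO with WT. Of the 25 cholesterol synthesis genes 21 fell in H-KO and 9 in BH-KO, and in BH-HF-KO no member of any list passed.

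Whether H-KO and BH-KO changed the same genes was asked from comparisons that share no libraries. Of the changed genes, 889 rose in both (317 by chance for independent lists) and 1121 fell in both (380 by chance), while 93 passed in opposite directions. The log2 fold changes of the 2 comparisons had a Pearson correlation of 0.59 and a Spearman correlation of 0.56 across 13958 genes, which are not independent replicates. The genes that fell at least 2-fold in H-KO had a median log2 fold change of -1.97 there, -1.02 in BH-KO and -0.00 in the libraries labelled BH-HF-KO. For those that rose, the medians were 1.74, 0.93 and -0.06. In single libraries, the median difference of the falling set from the WT group was -0.28 in BH-KO replicate 1 and -1.53 and -1.52 in replicates 2 and 3. The shared count of 2010 was 3228 without BH-KO replicate 1 and H-WT replicate 3, and 649 with each pair of groups fitted alone.

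**Figure D4:**
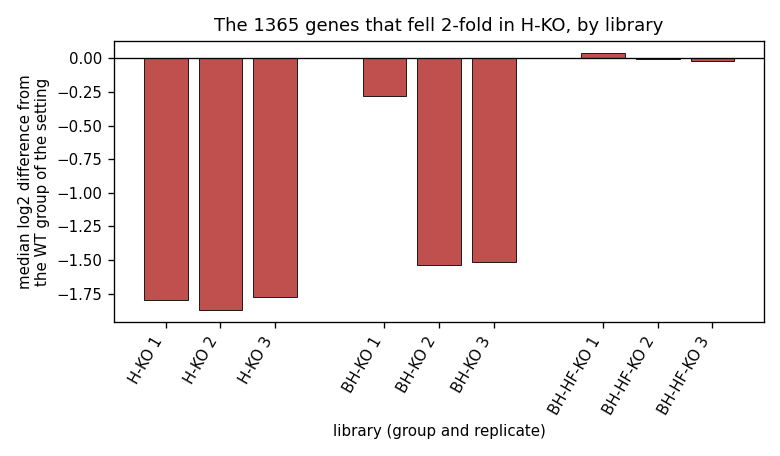
Median log2 difference from the WT mean of the same setting (vertical axis) over the 1365 genes that fell at least 2-fold in H-KO, a set chosen on the H libraries, in each KO library (bars). H-KO libraries reach -1.87 to -1.78, BH-KO replicate 1 reaches -0.28 beside -1.53 and -1.52, and the libraries labelled BH-HF-KO lie between -0.02 and 0.04.

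The interaction of the BH and H effects asks how the KO effect in the BH line differed from that in the H line. Higher and lower refer to the signed log2 fold change, so a higher effect can be a smaller fall. The effect on Arntl was higher in BH by 4.43 ± 0.59 (adjusted p = 0.000938), and that on Hnf4a differed by -0.04 ± 0.30 (adjusted p = 0.951). Of 24 clock genes, the effect was higher in BH for 7 and lower for 6, and 11 did not pass (16 adjusted over the list alone, camera adjusted p = 0.563). Of 20 pericentral genes, 9 had a higher effect in BH and 11 did not pass (12 adjusted over the list alone, median 1.55, camera adjusted p = 9.38e-07, adjusted p = 0.446 with an estimated correlation), and fry called this list too. Its median was -1.24 in H-KO and 0.10 in BH-KO against WT, so the higher value reflects a fall in H-KO that BH-KO lacked. Camera called the interferon list lower in BH (7 of 30 lower, 23 did not pass, 13 adjusted over the list alone, median -0.91, adjusted p = 1.05e-06). The macrophage list, of which 0 of 28 passed either way, was called lower too (median -2.01, adjusted p = 1.09e-05). For both the adjusted p was 0.789 with an estimated correlation, and fry did not call them. Both camera calls held without each library. The macrophage list had a median of -0.05 in H-KO and -1.44 in BH-KO against WT. Its median in BH-WT over H-WT was 1.52, and this difference between the controls is part of the contrast. Interferon genes lower in BH numbered 11, 2 and 2 without BH-KO replicates 1, 2 and 3, 2 and 1 without BH-WT replicates 2 and 3, 1 without any H-KO library, and 3, 1 and 2 without H-WT replicates 1, 2 and 3. Macrophage genes numbered 3 without BH-KO replicate 1 and 1 without BH-WT replicate 1. In total 846 genes differed, 525 higher and 321 lower in BH, and upper-quartile scaling gave 427 and 395. The count was 1247 without BH-KO replicate 1 and fell to 371 without BH-WT replicate 2, 457, 344 and 398 without H-KO replicates 1, 2 and 3, and 531 and 497 without H-WT replicates 2 and 3. DESeq2 gave 1394 genes, and 516 were called with no filter, 505 with sex as a covariate and 498 with the 4 groups fitted alone.

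The comparison of BH-HF-KO with BH-HF-WT asks how livers labelled KO differed from WT after 35 weeks of high-fat diet. No gene passed in edgeR, where 490 genes (3.51%) had an unadjusted p under 0.05. DESeq2 and limma-voom also gave 0 genes, with 448 and 443 at an unadjusted p under 0.05. Npas2 gave 0.849 ± 0.516 CPM in the libraries labelled BH-HF-KO and 0.185 ± 0.221 in BH-HF-WT (log2 fold change 2.19 ± 0.90, adjusted p = 1), Nr1d1 70.5 ± 9.97 and 44.3 ± 19.3 (0.67 ± 0.28, adjusted p = 1), and Dbp 103 ± 13.9 and 107 ± 23.1 (-0.04 ± 0.28, adjusted p = 1). Lpin1, a phosphatidate phosphatase of fat synthesis, gave 225 ± 24.8 and 391 ± 74.8 CPM (-0.80 ± 0.19, adjusted p = 1). Of 22 genes of fat synthesis none passed, 1 passed adjusted over the list alone, and the list was called lower by camera (median -0.33, adjusted p = 1.01e-07, adjusted p = 0.0929 with an estimated correlation). The 19 glycolysis genes, of which 0 passed either way, were also called lower (median -0.24, adjusted p = 0.00622, adjusted p = 0.0929 with an estimated correlation). Macrophage markers, of which 0 of 28 passed either way, were called lower as well (median -0.60, adjusted p = 0.0478, adjusted p = 0.888 with an estimated correlation). That call was lost without BH-HF-KO replicate 1 or 3 or BH-HF-WT replicate 1 or 3 (adjusted p up to 1). The neutrophil list, with 0 of 8 passed and a median of -1.46, was not called (adjusted p = 0.0891). Camera called 14 lists here and fry 0. Albumin took 3.06 ± 0.571% of counts in the libraries labelled BH-HF-KO and 6.85 ± 0.783% in BH-HF-WT (log2 fold change -1.18 ± 0.36, adjusted p = 1). Mitochondrially encoded genes took 8.26 to 9.92% in the former and 7.37 to 7.82% in the latter. The groups did not overlap for 10.4% of the tested genes, where chance gives 10%, and 1 gene passed without BH-HF-KO replicate 2. Of the genes that rose or fell at least 2-fold in BH-KO, 254 of 740 (34.3%) and 471 of 1053 (44.7%) had a 95% interval here that excluded an effect of 50% of the BH effect on the log2 scale.

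The interaction of the BH-HF and BH effects asks whether the KO effect differed with age, diet and time since tamoxifen, which changed together. The effect on Arntl was lower in BH-HF by -4.87 ± 0.61 (adjusted p = 0.000298), that on Cdkn1a by -6.71 ± 0.64 (adjusted p = 5.29e-05), and that on Hnf4a differed by 0.54 ± 0.30 (adjusted p = 0.291). Of 24 clock genes, the effect was higher in BH-HF for 9 and lower for 5, and 10 did not pass (17 adjusted over the list alone, median 0.41, camera adjusted p = 0.018, adjusted p = 0.81 with an estimated correlation). In total 851 genes differed, 481 higher and 370 lower in BH-HF, and upper-quartile scaling gave 430 and 549. The camera call for the clock list was lost without BH-KO replicate 1 (adjusted p = 0.108, the highest of a range from 0.0044 over the libraries left out). The count was 3046 without BH-KO replicate 1, 407 and 564 without BH-HF-KO replicates 1 and 2, 480, 522 and 559 without BH-HF-WT replicates 1, 2 and 3, 423 and 353 without BH-KO replicates 2 and 3, and 478 and 520 without BH-WT replicates 1 and 3. DESeq2 gave 1315 genes and the 4 groups fitted alone 431.

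BH-HF-WT and BH-WT ask how WT livers at 45 weeks on high fat differed from those at 10 weeks. Age, diet and time since tamoxifen, which the WT mice also received, cannot be separated here. Srebf1 (ENSMUSG00000020538, chromosome 11, 60199089 to 60222581), the regulator of fat synthesis, rose from 172 ± 25.9 to 609 ± 68.1 CPM (log2 fold change 1.83 ± 0.21, adjusted p = 0.0007). Acot3 (ENSMUSG00000021228, chromosome 12, 84052144 to 84060402), a peroxisomal thioesterase, fell from 164 ± 29.5 to 0.997 ± 0.692 CPM (-7.33 ± 0.92, adjusted p = 0.00132). The stress cytokine Gdf15 fell from 57.7 ± 22.4 to 2.01 ± 0.252 CPM (-4.83 ± 0.81, adjusted p = 0.00561). Nr1d1 fell from 120 ± 8.91 to 44.3 ± 19.3 CPM (-1.44 ± 0.28, adjusted p = 0.00971), the only 1 of 24 clock genes to pass, alone also adjusted over the list alone.

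Camera called 6 lists of this paragraph in BH-HF-WT against BH-WT, none of them with an estimated correlation (adjusted p = 0.437 for cholesterol synthesis, 0.484 for the female-biased list and 0.392 for the others). None was called by fry. Among male-biased liver genes, 6 of 21 rose in BH-HF-WT against BH-WT and 15 did not pass (11 adjusted over the list alone, median 2.42, camera adjusted p = 4.3e-08). Among female-biased genes 10 of 24 fell and 14 did not pass (14 adjusted over the list alone, median -7.28, or -6.73 with genes at 0 set to their bound, camera adjusted p = 0.000115). Cyp2a4, a female-biased P450 with close paralogs, gave 0.43 ± 0.408 against 399 ± 318 CPM (-9.78 ± 1.70, adjusted p = 0.00712). Mup14, a major urinary protein gene with near-identical copies, gave 1003 ± 314 against 11.6 ± 8.78 CPM (6.45 ± 0.83, adjusted p = 0.00138). Counts of both families are uncertain. The fat synthesis list had 5 of 22 genes that rose, 1 that fell and 16 that did not pass (11 adjusted over the list alone, median 0.53, camera adjusted p = 0.00319). Lpin1 rose from 154 ± 38.5 to 391 ± 74.8 CPM (1.34 ± 0.20, adjusted p = 0.00173) and the malic enzyme Me1 fell (-2.51 ± 0.46, adjusted p = 0.00872). Of 25 cholesterol synthesis genes 9 fell and 16 did not pass (14 adjusted over the list alone, median -0.91, camera adjusted p = 5.73e-08). Stellate cell and matrix genes fell in 10 of 32 cases, with 22 that did not pass (18 adjusted over the list alone, median -1.20, camera adjusted p = 1.91e-08). Macrophage genes fell in 5 of 28 cases, with 23 that did not pass (15 adjusted over the list alone, median -2.12, camera adjusted p = 1.91e-08), against a BH-WT group in which this list had a median of 1.52 over H-WT. In total 977 genes passed, 390 that rose and 587 that fell, 143 and 420 at least 2-fold, with 3389 at an unadjusted p under 0.05 and groups that did not overlap for 31% of genes (10% by chance). The count was 610, 255 and 411 without BH-HF-WT replicates 1, 2 and 3, 225 and 589 without BH-WT replicates 2 and 3, and 1495 in DESeq2. Without the same BH-HF-WT replicates 1, 2 and 3, then BH-WT replicates 1, 2 and 3, the male-biased rises numbered 2, 2, 3, 2, 0 and 1 and the macrophage falls 3, 1, 1, 8, 1 and 2. The female-biased falls numbered 5, 6 and 4 without the BH-HF-WT replicates and 4 and 6 without BH-WT replicates 2 and 3. The cholesterol falls numbered 0, 2 and 5 without BH-HF-WT replicate 2, BH-HF-WT replicate 3 and BH-WT replicate 3. The stellate falls numbered 0 without BH-HF-WT replicate 2 or 3 or BH-WT replicate 2. The fat synthesis rises numbered 3, 2 and 2 without BH-HF-WT replicate 1, BH-HF-WT replicate 2 and BH-WT replicate 2, with 2 falls without BH-HF-WT replicate 1.

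BH-HF-KO against BH-KO asks the same of mice labelled KO, but the libraries labelled BH-HF-KO lacked the Arntl level of BH-KO. Age, diet, time since tamoxifen and KO state are therefore not separated here. Mitochondrially encoded genes took 8.26 to 9.92% of counts in the libraries labelled BH-HF-KO and 9.45, 3.7 and 4.17% in BH-KO replicates 1, 2 and 3, and TMM factors were 0.83 to 0.899 and 0.881, 1.26 and 1.3. The camera calls of the 5 lists below did not hold with an estimated correlation (adjusted p = 0.371 for each). Of the 20 lists that camera called, fry called 16. Dbp was higher in the libraries labelled BH-HF-KO, at 103 ± 13.9 against 5.84 ± 2.83 CPM (log2 fold change 4.10 ± 0.33, adjusted p = 1.63e-06). Nr1d1 was at 70.5 ± 9.97 against 6.24 ± 0.682 CPM (3.50 ± 0.31, adjusted p = 4.5e-06). Npas2 was lower, at 0.849 ± 0.516 against 42 ± 5.15 CPM (-5.59 ± 0.53, adjusted p = 5.25e-06), and so was Arntl (-3.72 ± 0.38, adjusted p = 8.05e-06). Of 24 clock genes, 13 rose, 6 fell and 5 did not pass (19 adjusted over the list alone, camera adjusted p = 0.00955, lost without BH-KO replicate 1 with adjusted p = 0.0611, the highest of a range from 0.00407 over the libraries left out). Cebpa rose from 87.1 ± 1.24 to 435 ± 19.5 CPM (2.32 ± 0.13, adjusted p = 2.85e-08), in a list of 21 liver-enriched factors of which 7 rose, 1 fell and 13 did not pass (8 adjusted over the list alone, camera adjusted p = 0.000589). Of 30 urea cycle and amino acid breakdown genes 15 rose and 15 did not pass (17 adjusted over the list alone, median 0.68, camera adjusted p = 1.81e-06). Prodh2, of hydroxyproline breakdown, rose by 2.72 ± 0.52 (adjusted p = 0.00168). Of 21 p53 targets, 14 fell, 1 rose and 6 did not pass (17 adjusted over the list alone, median -0.85, camera adjusted p = 7.28e-05). Cdkn1a was at 2.61 ± 1.01 against 126 ± 26.4 CPM (-5.57 ± 0.38, adjusted p = 3.84e-07). Of 20 genes of the NRF2 and glutathione response, 10 fell and 10 did not pass (10 adjusted over the list alone, median -0.97, camera adjusted p = 0.00118), and 1 rose without BH-KO replicate 1. Gstm3, a glutathione transferase with close paralogs and an uncertain count, fell by 5.53 ± 0.50 on the log2 scale (adjusted p = 5.39e-06). The lipase gene Lpl fell by 4.12 ± 0.50 (adjusted p = 6.94e-05). In total 4368 genes passed, 2071 that rose and 2297 that fell, 946 and 1192 at least 2-fold, with 5865 at an unadjusted p under 0.05 and no overlap of the groups for 38.3% of genes (10% by chance). Upper-quartile scaling moved the median by -0.11 and gave 1704 rises and 3016 falls, and the 2 groups fitted alone gave 1755 genes.

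BH-WT against H-WT asks how the control mice of the lines differed. Nlrp12 (ENSMUSG00000078817, chromosome 7, 3218784 to 3249740), a regulator of inflammatory signalling, gave 41.6 ± 15.1 CPM in BH-WT and 0.26 ± 0.266 in H-WT (log2 fold change 7.22 ± 0.72, adjusted p = 0.000543). Trim12a (ENSMUSG00000066258, chromosome 7, 104299894 to 104315466), one of a cluster of related Trim genes and so uncertain in its count, gave 0.422 ± 0.245 and 14.1 ± 3.88 CPM (-5.03 ± 0.54, adjusted p = 0.000543). The phosphatase Acp1 gave 41.6 ± 3.16 and 19.3 ± 2.58 CPM (1.10 ± 0.13, adjusted p = 0.00068). Camera called the macrophage list (0 of 28 genes passed, also adjusted over the list alone, median 1.52, adjusted p = 3.66e-11) and the acute phase list (0 of 26 passed, also adjusted over the list alone, median 0.91, adjusted p = 3.66e-11) higher in BH-WT, with adjusted p = 0.882 for both with an estimated correlation. Fry called no list. In total 23 genes passed, 8 higher and 15 lower in BH-WT, and 1301 had an unadjusted p under 0.05. The count was 8, 7 and 11 without BH-WT replicates 1, 2 and 3, 8 without H-WT replicate 2, 62 without BH-KO replicate 1 and H-WT replicate 3, 35 with no filter, 101 in DESeq2 and 12 in limma-voom.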

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

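The splits of the libraries were chosen before the data were examined, while the tests of the explanations weighed here, and the fit without BH-KO replicate 1 and H-WT replicate 3, were chosen after the result was seen.

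The KO effect differed between the BH and H lines, by the interaction test, for 846 genes. On the log2 scale it was higher in BH by 10.15 for Elovl3, 7.96 for Hectd2os, 7.76 for Hsd3b2, 7.34 for Ces3b, 6.45 for Keg1, 6.31 for Npas2 and 4.43 for Arntl. It was lower in BH by -6.97 for Cntn2, -6.65 for Sorcs2, -6.57 for Ly6d, -6.26 for Rab44, -5.54 for Ptges and -5.52 for Lgi3. These are signed differences: Hsd3b2 and Ces3b fell and Sorcs2 rose in H-KO, so higher can mean a smaller fall and lower a smaller rise. Hectd2os is antisense to Hectd2 and Ces3b has a close paralog, so their counts are uncertain. Hectd2os, Cntn2, Ptges and Arntl passed without each library of the 4 groups. Hsd3b2 and Keg1 passed only when BH-KO replicate 2 or 3 was the library left out (adjusted p up to 0.101 and 0.0995). Ces3b did not pass without BH-KO replicate 1, any BH-WT, any H-KO or H-WT replicate 2 or 3 (up to 0.153), and Elovl3 without BH-WT replicate 2, any H-KO or H-WT replicate 2 (up to 0.0711), with 6.24 without BH-KO replicate 1. Npas2 did not pass without BH-WT replicate 1 or 3, any H-KO or H-WT replicate 1 or 3 (up to 0.164), with 9.65 without BH-WT replicate 2. Sorcs2 did not pass without BH-WT replicate 2 or 3, any H-KO or any H-WT (up to 0.154), Lgi3 without any BH-WT, any H-KO or H-WT replicate 1 or 3 (up to 0.108), Ly6d without BH-WT replicate 2 or H-KO replicate 2 (up to 0.0771), and Rab44 without BH-WT replicate 2 (0.287). Camera called the pericentral list (adjusted p = 9.38e-07) and the glycolysis list (adjusted p = 0.0271, and 0.0569 and 0.0616 without BH-KO replicate 2 and H-WT replicate 3). With an estimated correlation the adjusted p was 0.446 for both.

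The KO effect, with KO taken from the labels, differed between BH-HF and BH for 851 genes by the same test. It was higher in BH-HF by 8.84 for Saa2, 8.32 for Mup16, 8.14 for Mup17, 7.02 for Mup-ps13, 6.81 for Mup15 and 6.68 for Mup11, families of near-identical genes with uncertain counts. It was lower by -7.14 for Nckap5, -6.71 for Cdkn1a, -5.91 for Npas2, -5.41 for Cyp2c55, -4.95 for Grhl1, -4.94 for Gria3 and -4.87 for Arntl. Mup16, Mup-ps13, Mup11, Nckap5, Cdkn1a, Grhl1 and Arntl passed without each library of the 4 groups. Saa2 passed only when BH-HF-KO replicate 1 or 3 or BH-KO replicate 1 was the library left out (up to 0.157), with 4.26 without BH-HF-KO replicate 2. Mup17 did not pass without BH-HF-KO replicate 1, any BH-HF-WT, BH-KO replicate 2 or 3 or BH-WT replicate 1 or 3 (up to 0.0878), and Mup15 without these or BH-HF-KO replicate 2 (up to 0.113). Npas2 did not pass without BH-HF-KO replicate 1 or 2, BH-HF-WT replicate 2 or 3, BH-KO replicate 2 or 3 or BH-WT replicate 1 or 3 (up to 0.372), with -9.24 without BH-WT replicate 2. Gria3 did not pass without BH-HF-KO replicate 1 or 2, BH-HF-WT replicate 1 or 2, BH-KO replicate 2 or 3 or BH-WT replicate 1 or 3 (up to 0.161), and Cyp2c55 without any BH-HF or BH-WT library (up to 0.125). Camera called the clock list (adjusted p = 0.018, and 0.108 without BH-KO replicate 1) and the list of liver-enriched transcription factors (adjusted p = 0.018). With an estimated correlation the adjusted p was 0.81 for both.

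No gene passed between BH-HF-KO and BH-HF-WT in edgeR, DESeq2 or limma-voom, where 490, 448 and 443 genes had an unadjusted p under 0.05. Too much spread to see an effect of the size found at 10 weeks is argued against by the 1365 genes that fell in H-KO, whose lowest median in a library labelled BH-HF-KO was -0.0182, against -1.02 in BH-KO. An exchange of KO and WT labels among the 6 libraries is argued against by Npas2, with a highest value of 1.25 CPM where the BH-KO libraries held 37.9 to 47.8, if that change lasts to 45 weeks. Mice without the Cre allele at Alb stay open. Alb had a log2 fold change of -1.18, and the adjusted threshold could not decide, since no gene passed in this comparison. The share of Alb was lower in each library labelled BH-HF-KO (2.68 to 3.72%) than in each BH-HF-WT library (6.18 to 7.71%), which goes against this explanation. However, 10.4% of the tested genes had no overlap between these groups, and whether the WT mice carry the allele is not given. A loss of recombined hepatocytes over time, age and diet also may account for the pattern and were not tested.

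BH-KO replicate 1 had the clock gene levels of the other BH-KO libraries but little of the fall of the genes that fell in H-KO. A WT library under this label is argued against, since the smaller of its ratios of Npas2 and Arntl to the highest WT library was 7.26. A single share of unrecombined hepatocytes for both target genes is argued against, since 1052 of the genes that fell in H-KO (those at 5 CPM or more in BH-WT) stood at a median of 81.1% of BH-WT (32 and 32.4% in replicates 2 and 3), while 12 clock genes that fell in BH-KO in a fit without this library stood at 19.3% (19.7 and 18.5%). Incomplete recombination of Hnf4a alone, or another Hnf4a genotype, may account for it and was not tested.

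For each interaction, 100 splits of its 12 libraries, the real one included, were fitted alone. For BH against H, 2 of these, the real one included, gave at least the real count of 498 genes (highest other 820), a share under 0.05. The split that exchanged the setting of the KO libraries gave 464 genes. For BH-HF against BH, 7 of these, the real one included, gave at least the real count of 431 genes (highest other 3548). The highest count came from the split that exchanged the setting of the KO libraries. That split sets all BH against all BH-HF libraries, so its count holds the difference between these settings. Other splits can hold parts of such differences, so neither share measures chance, and chance is not excluded for either count. The splits also say nothing of single genes. For comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05. The real count and highest other were 5119 and 0 for H-KO, 1096 and 0 for BH-KO, 0 and 1 for BH-HF-KO, 839 and 0 for BH-HF-WT against BH-WT, 1755 and 0 for BH-HF-KO against BH-KO, and 18 and 1 for BH-WT against H-WT.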

How the results depend on the processing

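The fit without BH-KO replicate 1 and H-WT replicate 3 and the list tests without each library were added after the data were seen. The log2 fold change of no named gene changed sign in a passed call: of 14238 values for 824 gene comparisons, 12338 kept the side of the threshold, 1784 lost it and 116 gained it. With the compared groups fitted alone, genes that passed numbered 1096 in BH-KO, 498 for BH against H, 431 for BH-HF against BH and 1755 for BH-HF-KO against BH-KO, with 649 shared by H-KO and BH-KO. DESeq2 gave 1394 for BH against H, 1315 for BH-HF against BH, 1495 for BH-HF-WT against BH-WT and 101 for BH-WT against H-WT, where limma-voom gave 12. With no filter, 516 genes passed for BH against H and 35 for BH-WT against H-WT, and with sex as a covariate 505 for BH against H. Without BH-KO replicate 1 and H-WT replicate 3, 6198 passed in BH-KO, 3327 for BH-HF against BH and 62 for BH-WT against H-WT, and 3228 were shared by H-KO and BH-KO, against 4971 in H-KO, 884 for BH against H and 5953 for BH-HF-KO against BH-KO, within 1.5 times. The genes shared by H-KO and BH-KO numbered 879 at an adjusted p under 0.01 and 827 at 2-fold, where the stricter rule leaves fewer. Of 320 list tests camera called 135, 0 with an estimated correlation and 61 by fry, which asks another question. The cause of the other moves was not tested. Leaving out 1 library gave 3787 to 4284 genes in H-KO, 2330 to 5916 in BH-KO, 0 to 1 in BH-HF-KO, 344 to 1247 for BH against H, 353 to 3046 for BH-HF against BH, 225 to 1014 for BH-HF-WT against BH-WT, 2960 to 5693 for BH-HF-KO against BH-KO, 7 to 18 for BH-WT against H-WT and 118 to 140 list calls. The replicate numbers do not pair the samples: correlations of same-numbered samples ran from -0.25 to 0.06, and 2 of 18 correlated best with their own number. With the number as a block, 14 genes passed for BH-WT against H-WT, and 4649, 3665, 0, 649, 664, 738 and 4181 in H-KO, BH-KO, BH-HF-KO, BH against H, BH-HF against BH, BH-HF-WT against BH-WT and BH-HF-KO against BH-KO, with 133 list calls and 1882 shared genes. At 6846471 to 9816124 counts per library, a count of 0 does not exclude a level of up to 3 counts. That is 0.306 to 0.438 CPM relative to the plain total, before the TMM factor that the CPM values of genes include.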

Other observations

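The tests of genes near Arntl in this part were chosen after the result was seen.

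Lists of coagulation and complement and of apolipoprotein genes were called lower by camera in H-KO, though not with an estimated correlation (adjusted p = 0.654 and 0.473). Of 31 coagulation and complement genes, 20 fell, 1 rose and 10 did not pass (22 adjusted over the list alone, median -1.09, camera adjusted p = 6.71e-06). C9, of the membrane attack complex, fell from 414 ± 60.9 to 9.9 ± 3.49 CPM (log2 fold change -5.38 ± 1.21, adjusted p = 0.00394), and Mbl2, a lectin of complement activation, from 518 ± 180 to 18 ± 4.12 CPM (-4.85 ± 0.87, adjusted p = 0.000893). Of 24 apolipoprotein and lipoprotein secretion genes, 16 fell, 2 rose and 6 did not pass (20 adjusted over the list alone, median -1.38, camera adjusted p = 9.44e-06), with hepatic lipase, Lipc, at 4.3 ± 0.5 against 158 ± 31.1 CPM (-5.19 ± 0.88, adjusted p = 0.000658). No coagulation gene rose without H-KO replicate 1 or 2 or H-WT replicate 2 or 3. In the apolipoprotein list 1 gene rose without H-KO replicate 1 or H-WT replicate 2, and 0 without H-KO replicate 2 or H-WT replicate 1 or 3.

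In the libraries labelled BH-HF-KO, 11 of 22 fetal liver genes and 5 of 12 cholangiocyte genes were lower than in BH-KO, and 11 and 7 did not pass (12 and 6 adjusted over the lists alone, medians -1.56 and -0.95, camera adjusted p = 0.00829 and 0.0121, adjusted p = 0.371 for both with an estimated correlation). A fetal liver gene rose without BH-KO replicate 1 (1 gene). Saa2, an acute phase gene with close paralogs, was at 8699 CPM in BH-HF-KO replicate 2 and at 55.8 and 190 CPM in replicates 1 and 3.

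Of the 23 genes that differed between BH-WT and H-WT, 4 lay within 20 Mb of Arntl on chromosome 7 (17.4%, against 2.42% of the 13940 tested genes with a position, one-sided Fisher's exact p = 0.00207). The 4 genes were Trim5 (log2 fold change -5.97), Trim12a (-5.03), Gm1966 (-5.08) and Trim34b (6.02), paralogs or predicted genes with uncertain counts, chosen after their values were seen, and all 4 differed at least 2-fold the same way between BH-KO and H-KO. The Fisher test counts neighbours as independent, while the 3 Trim genes lie in 1 cluster. With neighbours counted once, 2 of 21 bins of 1 Mb that held such a gene lay in the window, against 35 of 1991 bins in all (one-sided Fisher's exact p = 0.0512). Called genes also lay near each other away from Arntl. Zfp125, CT010462.2 and Acp1 lay between positions 20877084 and 30911589 of chromosome 12, and no window other than that of Arntl was tested. Passenger DNA of the donor strain beside the Arntl allele and other strain differences between the lines both stay open. Nlrp12, on the same chromosome as Arntl, lay outside its window.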
